A study of Homo sapiens with 39 samples.

How the data were processed

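RNA of 39 pretreatment Wilms tumors was measured on Affymetrix arrays. Per the labels' protocols, total RNA was isolated with Trizol, treated with DNase I and turned into biotin-labelled cRNA. The deposited expression values are on a log2 scale and were made with RMA (background correction, quantile normalization and a summary per probeset), per the submitters' processing notes. The software version, the array annotation and the scan batches are not given in the sources used here. RMA draws the distributions of arrays together, so a change in the level of all genes at once cannot be seen in these values, and low levels are compressed towards the background. Arrays give no count of molecules, so the depth is unknown.

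The other source was the authors' deposited table of 239 probesets. It holds, for each of the 3 clusters against the other tumors, a signed fold change (a score that is negative where the cluster was lower), an unadjusted p-value and a call, all by the authors. Per the series text, the authors kept probesets with a value of at least 6.5 in some tumor, and called those with p under 1e-05 and a fold change over 2.5. Each deposited call met these thresholds. Under no difference at all, 0.145 of the 14452 probesets would pass the p threshold in a comparison of groups set without the values. The clusters were formed on these same values, so 0.145 is not the number of false calls expected here. The test behind the p-values is not given in the sources used here. The C1 fold change of 1 probeset is blank in the deposited table, and it followed from its other fold changes as 2.73. The series text counts 161 genes in the combined list, while the deposited table holds 181 distinct names.

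Only the deposited table paired probesets with genes. Of its 181 names, 123 were current symbols, 35 were updated through the synonyms of a RefSeq gene table (GRCh38.p14, used for names only) and 23 matched none and stayed as given; 17 probesets had no name. In the tumors' values, each gene was represented by its probeset with the highest mean. Of the 29 genes with over 1 probeset, 27 had the same calls for all of them, the exceptions being DCN and GUCY1B1, and the lowest correlation between 2 probesets of a gene was 0.867. Only probesets called in some comparison are in the table, which favors such agreement. No named gene of the table was Y-linked or XIST. Without a map of the array, probesets of such genes could not be left out of the 14452 probesets.

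Cluster sizes were derived from the deposited folds. With n tumors of N in a cluster and a ratio f of its mean to that of the rest, the cluster holds a share nf / (nf + N - n) of the summed unlogged signal, and the 3 shares must add to 1. Over 238 probesets the root mean square error was 5.06e-11 for sizes of 9, 13 and 17 and 0.00712 for the next best set. This holds for ratios of arithmetic means of unlogged values, so the deposited folds are of that kind and give weight to very high tumors. The mean level of each cluster then follows from the share and the sum over the 39 tumors, and none of the 717 means lay outside the range of the tumors. No tumor was assigned to a cluster.

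The gene lists, the relations, the main tests, the rule for naming genes and most of the alternatives were fixed before the data were examined. The rule named, for each comparison, the 15 called genes with the largest deposited fold change higher and the 10 lower, each list gene in the table and the 20 named genes with the largest SD. Random lists (10000) were matched on the mean level in 10 bins, and list tests needed at least 3 genes. Correlations used 100000 permutations, two-sided. Levels counted as separate clusters where a mixture of 2 normal distributions beat 1 by over 10 in BIC with Ashman's D over 2 and at least 3 tumors in each. Values were adjusted by Benjamini-Hochberg within each family, with a threshold of 0.05. Fisher's exact test was run within the named genes of the table, since the planned background of all measured genes needs a map of the array.

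The result of 1 gene that the rule takes in is not reported here. Several planned pieces were not run. WT1 and IGF2 are not named in the table, so the genes related to them, and 10 of the 14 relations, were not analysed here. The control probesets for RNA quality are not among the values used here, so the interquartile range of each array stood in for them, as a choice made after seeing the data. Replicate numbers were not used to pair tumors.

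The computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0. They were tested on simulated data. The cluster sizes were recovered in 4 of 4 simulated clusterings. For coherence, 100 of 100 simulated lists of 4 genes with a pairwise correlation of 0.5 were found and 3 of 100 unrelated lists were called. For relations, 99 of 100 simulated pairs with a correlation of 0.6 were found and 3 of 100 unrelated pairs were called. The mixture rule found 100 of 100 simulated splits of 30 and 9 tumors, 4 log2 units apart, and split 0 of 100 normally distributed single groups. Closer groups, skewed levels and random lists of genes that are themselves correlated were not simulated, so these rates need not hold for them.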

Results

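Gene expression was measured on 39 arrays, 1 per tumor, in Wilms tumors, the embryonal kidney tumors of childhood. All 39 were of favorable histology and were sampled before treatment, and the study placed them in its very low risk category. The labels put them in a single group, and each tumor counted as 1 sample. The study's question was whether such tumors form distinct subsets by expression, and its series text describes 3 clusters, called C1, C2 and C3. Which tumor belonged to which cluster is not given in the sources used here, and membership was not inferred. The comparisons of clusters therefore come from the authors' deposited table of 239 probesets, and the spread and the relations between genes were computed over the 39 tumors. The value table held 22215 probesets, of which 14452 reached a log2 level of 6.5 in at least 1 tumor. Array medians lay between 6.35 and 6.46, and the interquartile range of an array lay between 2.21 and 2.77 on the log2 scale. The correlation between any 2 tumors over the 14452 probesets ran from 0.806 to 0.976, and no 2 arrays were identical. The number of tumors limits the precision of every value computed here.

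The comparison of C1 with the other tumors asked which genes set that cluster apart. HLA-DMA, a chain of the chaperone that loads peptides onto class II molecules, was 20.3-fold higher in C1 in the authors' deposited table (p = 1.55e-08), IL1R1, the signalling receptor of interleukin-1, 17.5-fold and FBLN2, a matrix glycoprotein, 14.1-fold. In the other direction, the authors' deposited table gave MEIS2, a homeobox transcription factor, as 13.4-fold lower (p = 9.2e-07), IGF2BP3, an RNA-binding protein of fetal tissue, as 7.67-fold lower, HMGA2, a chromatin protein of fetal tissue, as 6.98-fold lower and SIX2, the transcription factor that maintains nephron progenitors, as 6.48-fold lower (p = 1.38e-11).

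C1 held most of the calls. The authors' deposited table listed 106 probesets, for 77 named genes, as higher in C1 and 55 probesets, for 44 named genes, as lower, with median fold changes of 3.88 and 3.36. Among named genes, the next largest increases in the authors' deposited table were in HS1119D91 (11.9-fold), GUCY1B1, a subunit of soluble guanylate cyclase (9.99-fold), MGAM, a brush border enzyme that digests starch (9.71-fold), AKR1C3, a steroid-metabolising reductase (8.99-fold), and FLJ20273 (8.98-fold). SQOR, CELF2, SORL1, KCNJ16, CCN2, PLOD2 and CLU lay between 7.93-fold and 5.97-fold higher in the authors' deposited table. Among the genes lower in C1, the authors' deposited table also had decorin (DCN, 10.8-fold), the imprinted zinc finger gene PLAGL1 (6.64-fold), KIAA0786 (6.30-fold), KIAA0416 (5.99-fold) and the collagen genes COL1A2 (5.42-fold) and COL6A2 (4.57-fold).

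Genes of several gene lists fixed beforehand were called in C1. No list was wholly in the authors' deposited table. It held 4 of 12 early nephron, 4 of 14 tubular epithelium, 4 of 14 fibroblast and matrix and 3 of 16 imprinted genes. Of the nephron progenitor genes it held 2 of 14, of mature kidney 1 of 16, of skeletal muscle 1 of 19 and of neurons 1 of 10. Results by list describe these called genes and not whole lists. Of the early nephron genes, the authors' deposited table called LHX1 (5.08-fold), JAG1, a Notch ligand (5.21-fold), and PAX8 (3.63-fold) higher in C1. Of the tubular epithelium genes, the keratins KRT8 and KRT18 were 5.13-fold and 3.20-fold higher in the authors' deposited table. GPX3 of mature kidney (5.02-fold), CCND1, which encodes cyclin D1, among the WNT targets (5.35-fold), GRB10 of the imprinted genes (2.91-fold) and VEGFA of the hypoxia genes (2.73-fold) were also higher in C1 in the authors' deposited table. The authors' deposited table called SIX2 and PLAGL1 lower, together with COL1A2 and DCN of the fibroblast and matrix genes, LEF1 of the WNT targets (3.65-fold), CHRNA1 of skeletal muscle (3.69-fold) and ELAVL4 of neurons (3.10-fold).

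The comparison of C2 with the other tumors gave a shorter list, with decorin and a fibrillar collagen near its top. Decorin was 8.07-fold higher in C2 in the authors' deposited table (p = 1.33e-06), EDNRA, an endothelin receptor, 6.69-fold, COL3A1, the collagen gene, 5.86-fold (p = 1.23e-09) and PDGFRA, a growth factor receptor of mesenchymal cells, 5.74-fold. The genes called lower in C2 were led in the authors' deposited table by MGAM (11.3-fold, p = 1.34e-06), FLJ10970 (6.17-fold), STAT4, a transcription factor of cytokine signalling (6.01-fold), ADGRG2, an adhesion receptor (4.15-fold), and the protease gene KLK6 (4.01-fold). In all, the authors' deposited table called 28 probesets, for 19 named genes, higher in C2 and 15 probesets, for 14 named genes, lower.

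Further genes higher in C2 in the authors' deposited table were KIAA0938 (5.18-fold), SPARCL1 (4.44-fold), SIM2 (4.37-fold), DKFZP564G2 (3.82-fold), LDB2 (3.75-fold) and PCOLCE, which aids procollagen processing (3.65-fold). TGFBI, LRRC17, EGFR, VCAN and PROM1 lay between 3.48-fold and 3.07-fold higher in the authors' deposited table. PNMA2, FLJ21610, ADAMTS3, S100A1 and FLJ10116 lay between 2.96-fold and 2.68-fold lower in the authors' deposited table. Of the 19 lists, only fibroblast and matrix had genes called in C2, with COL3A1, DCN and PDGFRA higher and COL1A2 not called. Within the 181 named genes of the authors' deposited table, 3 of the 4 fibroblast and matrix genes were among the 19 higher in C2 (Fisher's exact test, two-sided p = 0.00372, adjusted p = 0.0893 over 24 tests). This missed the threshold, and with probesets as the unit it passed (6 of 8 probesets, p = 4.48e-05, adjusted p = 0.00108), although probesets of 1 gene are not independent.

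The comparison of C3 with the other tumors was mostly one of lower levels. CCND1 was 8.80-fold lower in C3 in the authors' deposited table (p = 1.34e-09), and the RNA-binding protein gene CELF2, GUCY1B1 and AKR1C3 between 7.04-fold and 6.97-fold. CDKN1C, the imprinted inhibitor of cyclin-dependent kinases at 11p15, was 6.02-fold lower (p = 6e-12), and each of its 4 probesets in the authors' deposited table was called lower. Only called probesets are in that table, so any uncalled probeset of the gene is not seen. Among the genes higher in C3, the authors' deposited table had FLJ10970 (4.85-fold), ADGRG2 (4.02-fold), ITGA8, an integrin of kidney mesenchyme (3.22-fold, p = 5.08e-07), and MEIS2 (2.99-fold).

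The authors' deposited table called 17 probesets, for 16 named genes, higher in C3 and 54 probesets, for 38 named genes, lower. Among called genes, the other largest decreases in the authors' deposited table were in NRN1 (6.67-fold), SOX9, a transcription factor (4.90-fold), ARHGAP29 (4.48-fold), JAG1 (4.38-fold) and KIAA1102 (4.34-fold). Some uncalled genes had larger fold changes in C3, such as HLA-DMA (-10.9) and IL1R1 (-10.3). HAS2, which makes hyaluronan, BRINP1, WASF3, RAB27A, MMP23A, FGFR2, CEP15, KIAA0275, ITPR1, ANKRD6 and ATP2C1 lay between 2.95-fold and 2.57-fold higher in the authors' deposited table. By list, besides CCND1 and CDKN1C, the authors' deposited table called JAG1 and EMX2 (3.89-fold) of the early nephron genes lower in C3. It also called lower CDH1, which encodes E-cadherin (3.93-fold), and MAL (3.77-fold) of the tubular epithelium genes, MYLK of smooth muscle (2.77-fold) and VEGFA (2.91-fold), all in the authors' deposited table. ITGA8 was the only list gene called higher in C3 in the authors' deposited table.

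**Figure D1:**
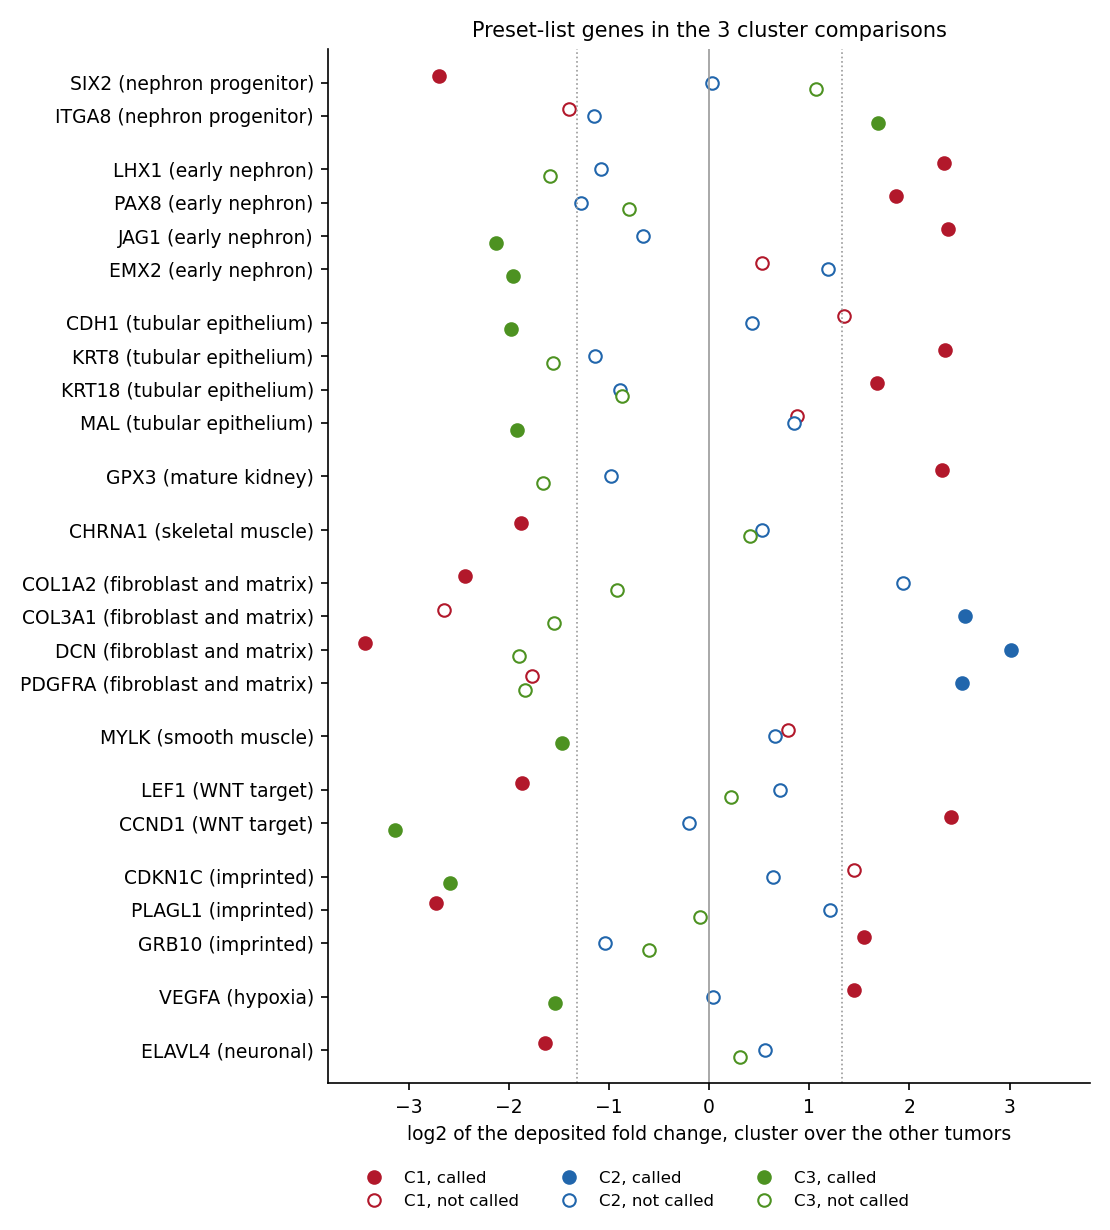
Rows are genes of the preset lists that are in the authors' deposited table, each with its probeset of the largest fold change. The x axis is the log2 of the deposited fold change of C1, C2 or C3 over the other tumors, filled points were called by the study, and dotted lines mark the fold threshold of 2.5. DCN lies farthest left for C1 (10.8-fold lower) and farthest right for C2 (8.07-fold higher), and CCND1 farthest left for C3 (8.80-fold lower).

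Other lists had no gene in the authors' deposited table: podocyte, cell cycle, macrophage, endothelium, erythroid, immediate early and adipocyte genes each had a count of 0. Which of these genes the array measures was not known here, so a count of 0 does not show that they were alike in the clusters. Within the table, the adjusted p was 1 in the gene-level tests of the early nephron, tubular epithelium and imprinted lists, and lists with under 3 genes there were not tested. The tumors were clustered on the same values from which these genes were chosen, so the deposited p-values and the directions of list genes are not independent evidence that the clusters differ.

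Several genes were called in more than 1 comparison, always in opposite directions. The authors' deposited table had 19 probesets, for 13 genes, that were both higher in C1 and lower in C3, among them CCND1, CELF2, JAG1 and VEGFA, where 0.396 would be shared by independent lists. DCN was among the 5 probesets lower in C1 and higher in C2, MGAM among the 5 higher in C1 and lower in C2, MEIS2 among the 4 lower in C1 and higher in C3, and ADGRG2 among the 3 lower in C2 and higher in C3 in the authors' deposited table. Such overlaps have a built-in part, since each cluster belongs to the tumors against which the others were set. Across the probesets of the authors' deposited table, the log2 fold changes correlated at -0.67 between C1 and C2, -0.63 between C1 and C3 and -0.11 between C2 and C3. The means over 100 random splits of the tumors were -0.33, -0.51 and -0.56. The splits ranged from -0.92 to 0.43, -0.92 to 0.37 and -0.92 to 0.35, so each observed correlation lay within them. The covariances were -1.52, -1.37 and -0.15, against -0.08, -0.10 and -0.10 in the random splits. The probesets were chosen for large fold changes between these clusters, so larger covariances than in random splits were built in.

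The deposited fold changes also fixed the sizes and mean levels of the clusters, without saying which tumor was where. Sizes of 9 tumors in C1, 13 in C2 and 17 in C3 satisfied the arithmetic that ties the 3 fold changes of a probeset together, as none of the rest of the 703 possible sets of sizes did. From the mean levels that follow from the authors' deposited table, HMGA2 was 6.78 times as high in C2 and 7.13 times as high in C3 as in C1. The 2 probesets of SIX2 were 4.13 and 5.29 times as high in C2 and 6.73 and 7.39 times as high in C3 as in C1, by the authors' deposited table. Over its 4 probesets, DCN was 8.74 to 20.6 times as high in C2 as in C1 and 3.90 to 6.11 times as high in C2 as in C3, by the authors' deposited table. The 4 probesets of CDKN1C were 1.30 to 1.48 times as high in C1 as in C2 and 2.88 to 5.02 times as high in C2 as in C3, from the authors' deposited table. For each call in the authors' deposited table the named cluster's mean lay beyond both other means. It did so by over 1.5-fold in 106 of 106 probesets higher and 53 of 55 lower in C1, in 28 of 28 and 14 of 15 in C2, and in 17 of 17 and 54 of 54 in C3, from the authors' deposited table. These means carry no error, since the spread within a cluster is not known here.

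Over the 39 tumors, the named genes of the table varied far more than most of the array. MEIS2 had the largest spread, with a log2 level of 8.46 ± 2.11 (SD, n = 39), followed by MGAM at 6.53 ± 1.99 (SD, n = 39), HLA-DMA at 7.36 ± 1.94 (SD, n = 39), IL1R1 at 7.41 ± 1.90 (SD, n = 39) and CCND1 at 7.46 ± 1.82 (SD, n = 39). COL3A1 spanned a 113-fold range between its lowest and highest tumor, MEIS2 98.4-fold and IL1R1 70.1-fold. The median SD was 1.08 over the 239 probesets of the table and 0.32 over the 14452 probesets, of which 1.83% reached the table's median. The other genes among the 20 with the largest SD were KCNJ16, FLJ10970, FLJ20273, IGF2BP3, DCN, FBLN2, EMX2, PLOD2, HS1119D91, NRN1, GUCY1B1, AKR1C3, CELF2 and STAT4, with SDs from 1.75 down to 1.58.

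**Figure D2:**
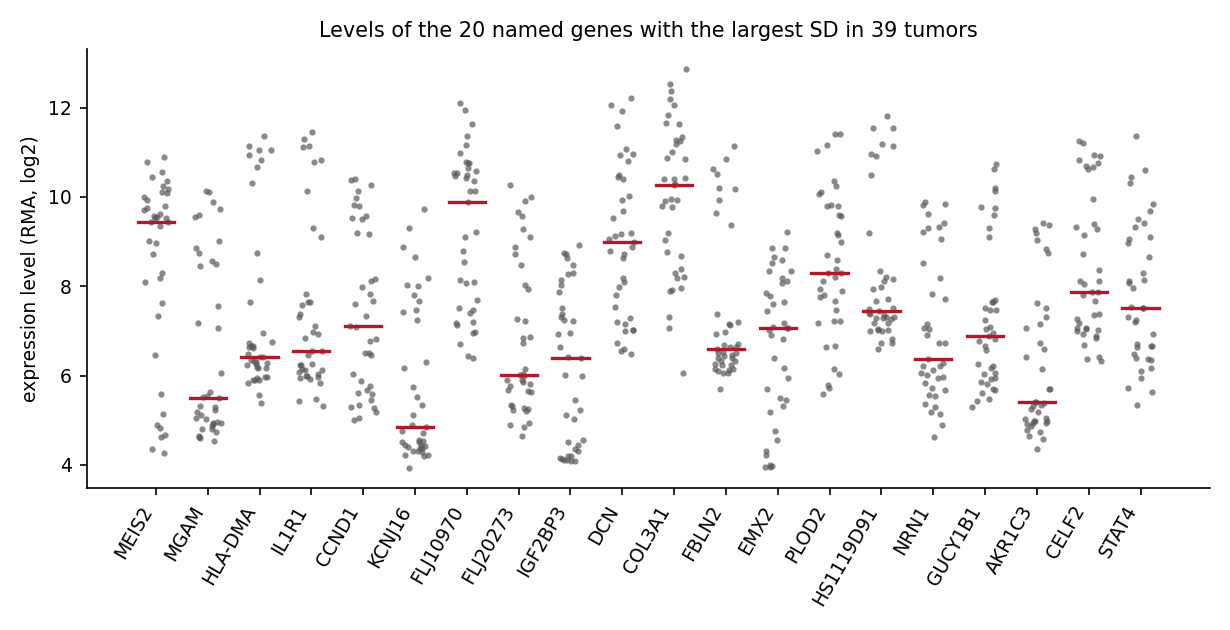
Each point is 1 of the 39 tumors, the y axis is the log2 expression level, the bars are medians, and the genes on the x axis are ordered by SD from MEIS2 to STAT4. FBLN2 and IL1R1 each show 9 tumors above and 30 below a gap, and by the mixture rule 9 tumors formed the lower cluster of MEIS2.

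For 40 of the 181 genes the levels fell into 2 separate clusters by a mixture rule fixed beforehand. FBLN2 was high in 9 tumors and low in 30, with a highest level of 11.14 and a median of 6.59, and IL1R1, GUCY1B1, SQOR and SORL1 split 9 to 30 as well. MEIS2 was low in 9 tumors, SIX2 in 12 and HMGA2 in 10. Sizes varied, with 15 tumors in the upper cluster of MGAM and 11 in that of HLA-DMA. A cluster of 9 tumors was found in 12 of the 40 genes. In 30 of the 40 genes the smaller cluster was the upper 1. All 181 genes entered the table for differing between the study's clusters of tumors, so their choice favored such splits. The rule's result for probesets outside the table is not given here, so these counts are no independent evidence of separate groups. Low levels are compressed in these values, and whether skewed levels account for part of the upper clusters was not tested.

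The 4 fibroblast and matrix genes of the table varied most among the lists that had at least 3 genes there. The median SD was 1.61 for the fibroblast and matrix genes COL1A2, COL3A1, DCN and PDGFRA, 1.37 for the imprinted genes CDKN1C, PLAGL1 and GRB10, 1.33 for the tubular epithelium genes and 1.28 for the early nephron genes. Random lists matched on expression had medians between 0.30 and 0.33, and each of the 4 lists lay above them (two-sided resampling p = 0.0002, the smallest that 10000 lists can give, adjusted p = 0.0002). The genes entered the table for differing between clusters, so this excess was built in. Against random genes of the table only the fibroblast and matrix list stood out (adjusted p = 0.036), and the adjusted p was 0.255 for each of the others.

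The 4 fibroblast and matrix genes of the table varied together across tumors, more closely than random table genes sharing a call with them. The mean pairwise rho was 0.842 for the fibroblast and matrix genes, 0.665 for CDH1, KRT8, KRT18 and MAL of the tubular epithelium list and 0.499 for LHX1, PAX8, JAG1 and EMX2 of the early nephron list. Each exceeded random lists matched on expression (one-sided resampling, adjusted p = 0.0002, 0.0002 and 0.00133 over the 4 lists). The imprinted genes CDKN1C, PLAGL1 and GRB10 did not vary together, with a mean rho of -0.0762 (adjusted p = 0.718). GRB10 was called higher and PLAGL1 lower in C1, so their choice favored a low rho. Genes with the same cluster calls vary together by their choice, and against random table genes that share a call with each list gene only the fibroblast and matrix list passed (random median rho 0.443, adjusted p = 0.0004). The tubular epithelium genes (random median rho 0.527, adjusted p = 0.251), the early nephron genes (random median rho 0.520, adjusted p = 0.590) and the imprinted genes (random median rho -0.129, adjusted p = 0.467) did not. The shared call matched neither the fold changes in the other comparisons nor the spread. How far these account for the fibroblast and matrix result was therefore not settled. Among these genes, the levels of MAL and LHX1 fell into separate clusters of tumors.

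Tumors with higher early nephron scores had higher tubular epithelium scores, and tumors with higher nephron progenitor scores had lower ones. Neither relation differed from that of random table genes sharing a call with each list gene. The score of a list was the mean of its standardised genes in the table, so most genes of each list were absent from it. None of the scores fell into separate clusters. Of 14 planned relations, 4 could be computed. The early nephron and tubular epithelium scores had r = 0.877 and rho = 0.896 over 39 tumors (permutation p = 1e-05 for both, the smallest that 100000 permutations can give, adjusted p = 2e-05 and 4e-05), and r = 0.872 without the 2 tumors farthest from the median. The nephron progenitor score, of SIX2 and ITGA8, and the tubular epithelium score had r = -0.676 (permutation p = 1e-05, adjusted p = 2e-05) and rho = -0.624 (permutation p = 2e-05, adjusted p = 4e-05), and r = -0.610 without the 2 farthest tumors. Given the interquartile range of each array, the partial r was 0.873 and -0.685. Scores of random table genes that share a call with each list gene had a median r of 0.888 for the first relation and -0.711 for the second (adjusted p = 0.959 for both), so neither differed from what the choice of genes by cluster call gives.

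The fibroblast and matrix score was not related to the nephron progenitor score, with r = 0.0473 (permutation p = 0.773, adjusted p = 0.773) and rho = 0.0105 (permutation p = 0.949, adjusted p = 0.949), and r = -0.0033 without the 2 farthest tumors. Its relation with the tubular epithelium score had r = -0.324 (permutation p = 0.0442, adjusted p = 0.0589) and rho = -0.35 (permutation p = 0.0291, adjusted p = 0.0388), so that only the rank correlation passed after adjustment. Scores of random table genes that share a call with each list gene had a median r of 0.283 for the first of these relations and -0.334 for the second (adjusted p = 0.959 for both), so neither was told apart from what the choice of genes gives. Without the 2 farthest tumors r was -0.306 (permutation p = 0.065), and the partial r given the interquartile range of the array was -0.282 (permutation p = 0.0806).

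**Figure D3:**
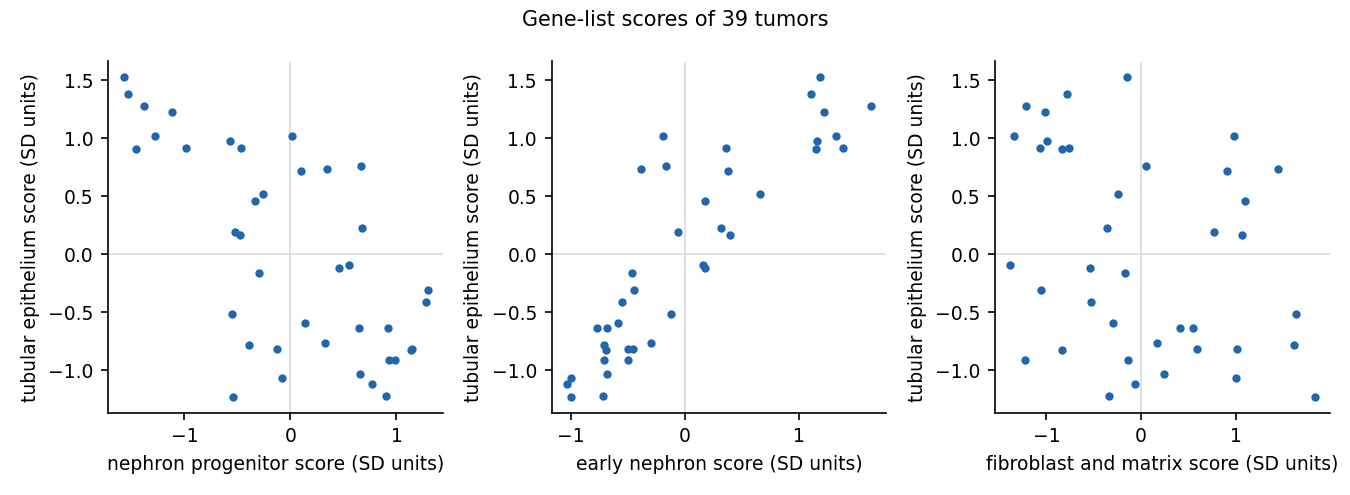
Each point is 1 of the 39 tumors. The y axis is the tubular epithelium score and the x axes are the nephron progenitor, early nephron and fibroblast and matrix scores, each in SD units, with grey lines at 0, for r = -0.676, 0.877 and -0.324.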

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

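The references drawn from the table and the corrections for the interquartile range of the array were chosen after seeing the data. With a fold threshold of 4, the authors' deposited table kept 89 of its 239 probesets: 47 higher and 20 lower in C1, 12 and 5 in C2, and 3 and 15 in C3, as a stricter threshold must give fewer. With probesets as the unit, 1 list test passed (fibroblast and matrix, higher in C2), against 0 with genes, the probesets of a gene being counted separately. The coherence of the early nephron genes, a mean rho of 0.499, passed against matched lists and not against random genes of the table (adjusted p = 0.0843), whose random rho spread more widely, with a 95th percentile of 0.525 against 0.223. Against random table genes that share a call with each list gene, neither it (adjusted p = 0.590) nor the tubular epithelium genes (mean rho 0.665, adjusted p = 0.251) passed. Neither did r = -0.676 of the nephron progenitor and r = 0.877 of the early nephron with the tubular epithelium score (adjusted p = 0.959 for both). The lowest adjusted p over the settings was 0.000133 for both lists and 2e-05 for both relations. The fibroblast and matrix score against the tubular epithelium score passed as rho = -0.35 (adjusted p = 0.0388) and not as r, with adjusted p from 0.0388 to 0.959 over the settings; why rank and linear correlation differed was not tested. The uncalled r of the nephron progenitor and the fibroblast and matrix scores went from 0.0473 to -0.0033 without the 2 farthest tumors, which is a change of sign at no relation. The other 62 values kept their direction and their side of the threshold. The early nephron and tubular epithelium relation ran from 0.872 to 0.896, and that of the nephron progenitor and tubular epithelium scores from -0.685 to -0.610. The spread of each list passed against matched lists in every setting (highest adjusted p = 0.0008). Against random genes of the table the median SDs of 1.28 (early nephron), 1.33 (tubular epithelium) and 1.37 (imprinted) no longer passed (adjusted p = 0.255 for each), since those genes were chosen for differing between tumors. Filters on low values could move little, since leaving the filter out changed no gene of the table and the stricter limit of 8 removed 7 genes, 0 of them in the tested lists. Not run were both planned backgrounds of Fisher's test, the corrections by control probesets, and all settings for genes related to WT1 and IGF2. No paired analysis was possible because the tumors form 1 group. Signal over background is not part of the values used here, so how far low levels are compressed stays unknown.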

Other observations

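The genes that vary together were picked after their calls and correlations were seen, and the tests of another cluster's level and of the choice of genes by cluster calls were chosen after the results were seen. The tests with the interquartile range of the array, those of the principal components included, were also chosen after seeing the data. JAG1, a Notch ligand, was 5.21-fold, NOTCH3, a Notch receptor, 3.07-fold and the transcription factor gene HEY1 3.20-fold higher in C1 in the authors' deposited table, and HEY2 was called lower in C3 with a fold change of -3.94. HLA-DMB, the partner chain of HLA-DMA, was 4.86-fold higher in C1 in the authors' deposited table, and GUCY1A1, the partner subunit of GUCY1B1, 2.95-fold. PLAG1, a zinc finger gene, had a fold change of -3.90 in C1 in the authors' deposited table, beside the lower HMGA2 and IGF2BP3.

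The hypothesis that each of these sets varies together was set beside random sets of table genes, over the tumors of the larger cluster of levels where a member fell into separate clusters. The random genes were called higher in C1 or lower in C3, or for HMGA2, PLAG1 and IGF2BP3 lower in C1 or higher in C3. JAG1, NOTCH3, HEY1 and HEY2 had a mean rho of 0.736 over 39 tumors, against a random median of 0.519. GUCY1A1 and GUCY1B1 had a rho of 0.774 over 30 tumors, against 0.186. HMGA2, PLAG1 and IGF2BP3 had a mean rho of 0.594 over 22 tumors, against 0.0563, and HLA-DMA and HLA-DMB a rho of 0.453 over 28 tumors, against 0.197. The random 95th percentiles were 0.676, 0.670, 0.544 and 0.681 in the same order, and only HLA-DMA with HLA-DMB lay below its own. As the genes were picked for this pattern, these values describe these tumors and decide none of the hypotheses.

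In the authors' deposited table, counting either direction, 4 probesets for C1, 11 for C2 and 9 for C3 had a fold change over 2 and a p over 0.05, among them DCN in C3 and IL1R1 in C2. A candidate explanation is that the level of 1 other cluster carries the fold, since the cluster's mean lay between those of the other clusters in 22 of the 24 (91.7%), against 28 of the 444 fold changes over 2 with a smaller p (6.31%). The test set beforehand, a mean within 1.5-fold of another cluster's, held in 8 of the 24 and would have argued against this, but a cluster that lies between the others need not be close to either. Another is that a few very high tumors pull up arithmetic means, since the median log2 ratio of arithmetic to geometric mean was 0.89 in these 24 probesets and 0.39 in the other 215, a difference of 0.50 (one-sided permutation p = 0.0001, the smallest that 10000 draws can give). A cluster of high tumors would give both values, so the tests do not separate the 2 explanations. The 24 probesets were chosen for a large ratio of arithmetic means with a weak p, which may itself favor a high ratio of arithmetic to geometric mean. Some are probesets of the same gene and not independent, so the permutation p is no independent evidence for either explanation.

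CCND1, CELF2 and JAG1 were among the 19 probesets called higher in C1 and lower in C3 in the authors' deposited table. Such a call would arise from C1 alone if C2 and C3 were alike. In these probesets C2 and C3 were not alike: the mean of C2 was over 1.5 times that of C3 in 19 of the 19 (100%). The median ratio was 2.23 and the lowest 1.72, from the authors' deposited table. A call of lower in C3 favors such a ratio, as all 54 probesets called so lay below both other means by over 1.5-fold. The ratios therefore describe the 19 probesets and are no independent test of that explanation. The means thus ran C1 over C2 over C3 in all 19 of these probesets, and no biological explanation was tested.

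The inverse relation of the nephron progenitor and tubular epithelium scores may come from how the genes were chosen. Of 10000 pairs of random scores, 48.5% had a lower r than the -0.676 observed. Their genes were called lower in C1 or higher in C3 for the first score and the reverse for the second. SIX2 and ITGA8 were thus not more opposed to KRT8, KRT18, CDH1 and MAL than other genes of the table called in these directions were. The spread of values on the array did not account for it, with a partial r of -0.685 given the interquartile range (permutation p = 1e-05, the smallest that 100000 permutations can give). A developmental order of the tumors stays open as an untested biological explanation.

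The first 3 principal components of the 14452 probesets held 20.7%, 16.1% and 9.72% of the variance, and each was related to the interquartile range of the array. For the first, whose values fell into separate clusters, the size of r was 0.759 and that of rho 0.711 in the larger cluster of 29 tumors (permutation p = 1e-05 and 7e-05, adjusted p = 3e-05 and 0.000135), and r was 0.700 in size without the 2 farthest tumors. For the second and the third, over 39 tumors, the size of r was 0.595 and 0.523 (permutation p = 8e-05 and 0.00056, adjusted p = 0.00012 and 0.00056), that of rho 0.565 and 0.594 (permutation p = 0.00021 and 9e-05, adjusted p = 0.00021 and 0.000135), and that of r without the 2 farthest tumors 0.497 and 0.616. Whether the interquartile range is a trait of the tumors or of the arrays was not tested. Outside the table, 20 of the kept probesets had an SD over 1.5, against 34 within it, and they carry no gene name here.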
